A study of Mus musculus with 4 samples.

How the data were processed

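Gene expression was measured by RNA sequencing of uterine implantation sites taken on day 8 of pregnancy from CD-1 mice, an outbred stock. Females received PRT4165 or vehicle alone 2 times per day from day 5 to day 7. Per the labels' protocols, poly(A) RNA was made into stranded libraries by the dUTP method and sequenced on an Illumina HiSeq instrument as paired-end reads of 75 bp. There were 2 vehicle and 2 PRT4165 libraries, grouped by their labels. Nothing in the labels says whether the libraries of a group came from separate animals, from several sites of 1 animal or from pools. Most p-values therefore measure only the spread between these samples, which may be technical. Exceptions are gene-list p-values at a preset correlation and those from shuffled genes, which rest on the spread between genes. These do not measure variation between animals either.

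The authors deposited, for each library, a table of 26099 rows with a whole-number read count and an RPKM value (a read count scaled by length and depth), per the file headers. Each row stands for a group of RefSeq transcripts that share a transcription start, per the file headers. Reads were aligned with STAR 2.4.2a, per the submitters' processing notes, which name the builds hg19 and mm10; the mouse coordinates here are those of mm10. The counting program, its strand setting and its treatment of reads with several matches are not given in the sources used here. Even counts made up 58.1% to 63.8% of the counts below 1000 in the deposited tables, so both mates of a read pair appear to have been counted, and counting error is larger than the counts alone give. Genes on opposite strands that overlap could not be told apart with certainty for the same lack of a stated setting.

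Counts of rows that shared a symbol, chromosome and strand and overlapped were summed, which gave 23791 genes, 1837 of them from several rows. Some overlapping rows of different symbols, such as Hbb-b1 and Hbb-bs, had identical counts. Reads may therefore enter several overlapping rows, and the sums may hold some reads repeatedly. Symbols found at several loci (234) were kept apart by locus. Genes were tested with edgeR 4.0.16 in R 4.3.3: normalisation factors by TMM, the default expression filter (filterByExpr), and the two-sided quasi-likelihood test of PRT4165 against vehicle, with Benjamini-Hochberg adjustment and a threshold of 0.05 over 15954 tested genes. All 4 libraries entered the fit, with group as the only term. Levels are TMM-scaled CPM (counts scaled to library depth), as mean ± SD over the n = 2 libraries of a group. Log2 fold changes are PRT4165 over vehicle, with their standard errors (SE). A gene with no count in a group was given a fold against a floor of 3 counts over the group. That fold is not a strict lower bound. Both mates of a pair appear to have been counted, and the error of the higher group is left out. The deposited RPKM values were used only in alternatives, as log2(RPKM + 1) and log2(RPKM + 0.1) tested with limma 3.58.1.

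Before the data were examined, 38 gene lists were fixed. They cover the complex that PRT4165 targets, decidual function, the cell cycle, matrix, signalling, stress and the cell types an implantation site holds. The 36 lists with at least 3 tested members were tested with camera (limma) at a preset inter-gene correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over lists. The tests were repeated with an estimated correlation and with fry. With an estimated correlation camera judges a list by the few residual degrees of freedom of 4 libraries, so hardly any list could pass. Camera compares a list with all other genes, and fry does not. The mitochondrially encoded list had 0 members in the tables.

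The genes named in the text were chosen by a rule also fixed before the data were examined. They are the 10 largest increases and 10 largest decreases among genes past the threshold with a mean of at least 2 CPM and both PRT4165 libraries beyond both vehicle libraries. From each list, the rule takes up to 4 members past the threshold with the smallest p (up to 2 where none passed), and it always takes Ring1, Rnf2, Bmi1, Cbx4, Cbx2, Rybp, Ezh2, Prl8a2, Bmp2, Wnt4, Hoxa10 and Pgr. Other genes are named only where the text says that they were chosen after their values were seen. The rule gave 163 genes, and 158 of them overlapped a GENCODE M21 gene of the same symbol, from which gene types were taken.

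Total counts were 45221450 and 69432832 in the vehicle libraries and 76737029 and 80449996 in the PRT4165 libraries. A floor of 3 counts stood for 0.0663 and 0.0432 CPM in vehicle and for 0.0391 and 0.0373 CPM under PRT4165. Such floors cover at most counting error, since the mates of a pair and amplified reads are not independent molecules. Rn45s, the ribosomal precursor RNA, took 1.64% of the counts of vehicle library 1 and 0.631%, 0.575% and 0.677% of those of vehicle library 2, PRT4165 library 1 and PRT4165 library 2.

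The procedure was tested on simulated counts for the comparison of PRT4165 with vehicle, in which 200 of 15954 genes were changed. It called 72% of the genes changed 1.3-fold, 88% of those changed 1.5-fold and 100% of those changed 2-fold or 4-fold, each with the right sign. It also called 9 unchanged genes. In a separate simulation only the smooth muscle list was shifted, by 1.41-fold. Of the lists, 1 was called there, which was the shifted list. The simulations gave both groups the same spread and drew all libraries and genes independently, so correlation between genes was absent. The simulation of single genes changed only genes of at least 2 CPM. In the real data the PRT4165 pair was closer than the vehicle pair, and both mates of a pair appear to have been counted. These shares and false calls therefore need not hold there.

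Alternatives fixed before the data were examined were other normalisations, filters and thresholds, DESeq2 1.42.0, limma-voom, the RPKM tests, a replicate block, robust dispersion and each library left out in turn. With 1 library left out, the lone library of its group was assumed to vary like the pair of the other group. Alternatives added after seeing the data were the rows as deposited, the libraries of a group summed to 1 sample, counts divided by 2, the tables without Rn45s, a 2-fold minimum and genes with the same 4 counts kept once. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9 were used for tables and plots.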

Results

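RNA was measured in implantation sites of the mouse uterus on day 8 of pregnancy. These sites hold the decidua (uterine stroma remodelled around the embryo), the surrounding uterine wall, maternal blood and immune cells, and the early conceptus. PRT4165 is a small molecule that inhibits the histone H2A ubiquitin ligase activity of Ring1 and Rnf2, the catalytic subunits of Polycomb repressive complex 1 (PRC1). It was injected at 4 mg/kg in 0.1 ml of sesame oil with 10% ethanol, 2 times per day from day 5 to day 7, and controls received the oil and ethanol alone. There were 2 libraries per group. Total counts were 45221450 and 69432832 for vehicle and 76737029 and 80449996 for PRT4165. The comparison asks how PRT4165 given after implantation alters gene expression at the site where stromal cells decidualize. Only RNA was analysed here, so whether PRC1 was inhibited at the site was not tested.

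By camera at a preset correlation between genes, lists of contractile smooth muscle, matrix glycoprotein, cathepsin, macrophage, yolk sac and adult haemoglobin genes were higher under PRT4165, and mitosis, DNA replication, polyploidy, PRC2 and neutrophil lists were lower. With an estimated correlation 0 of the 36 lists passed. Falls among mitosis genes numbered 23, but 8 without either PRT4165 library, and among DNA replication genes 11, but 2 and 1 without PRT4165 library 1 and 2. Myh11, the smooth muscle myosin heavy chain, rose from 607 ± 22.3 to 981 ± 7.52 CPM (SD, n = 2 per group; log2 fold change 0.69, SE 0.034, adjusted p = 5.2e-07). Timp3, an inhibitor of matrix metalloproteinases, fell from 923 ± 55.8 to 331 ± 1.55 CPM (n = 2 per group; log2 fold change -1.48, SE 0.042, adjusted p = 1.3e-08). Markers of decidualization went both ways: 9 of 31 rose and 11 fell (5 and 7 without PRT4165 library 1, 6 and 7 without PRT4165 library 2). Of 15954 genes tested with edgeR's quasi-likelihood test, 1731 were higher and 1697 lower at an adjusted p under 0.05. With library size as the only scaling the split was 1408 higher and 2276 lower. Most changes were small, with a median absolute log2 fold change of 0.31 among changed genes; 412 genes were higher and 267 lower by at least 1.5-fold, and 165 and 118 by at least 2-fold. Libraries of the 2 groups did not overlap for 62.0% of tested genes. Chance gives 33.3% if all libraries vary alike, but more where 1 pair is closer, as the PRT4165 pair was.

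These counts rested on the closeness of the PRT4165 pair. They were 646 higher and 468 lower without PRT4165 library 1, 708 and 528 without PRT4165 library 2, 2680 and 2882 without vehicle library 1, and 3464 and 3301 without vehicle library 2. Counts within the lists moved too. Where one moved by over 1.5 times, V1, V2, P1 and P2 below give the numbers risen/fallen without vehicle library 1 or 2 and without PRT4165 library 1 or 2. Vehicle library 1 had the lowest total count and the highest Rn45s share, 1.64% against 0.575% to 0.677% in the other libraries.

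**Figure D1:**
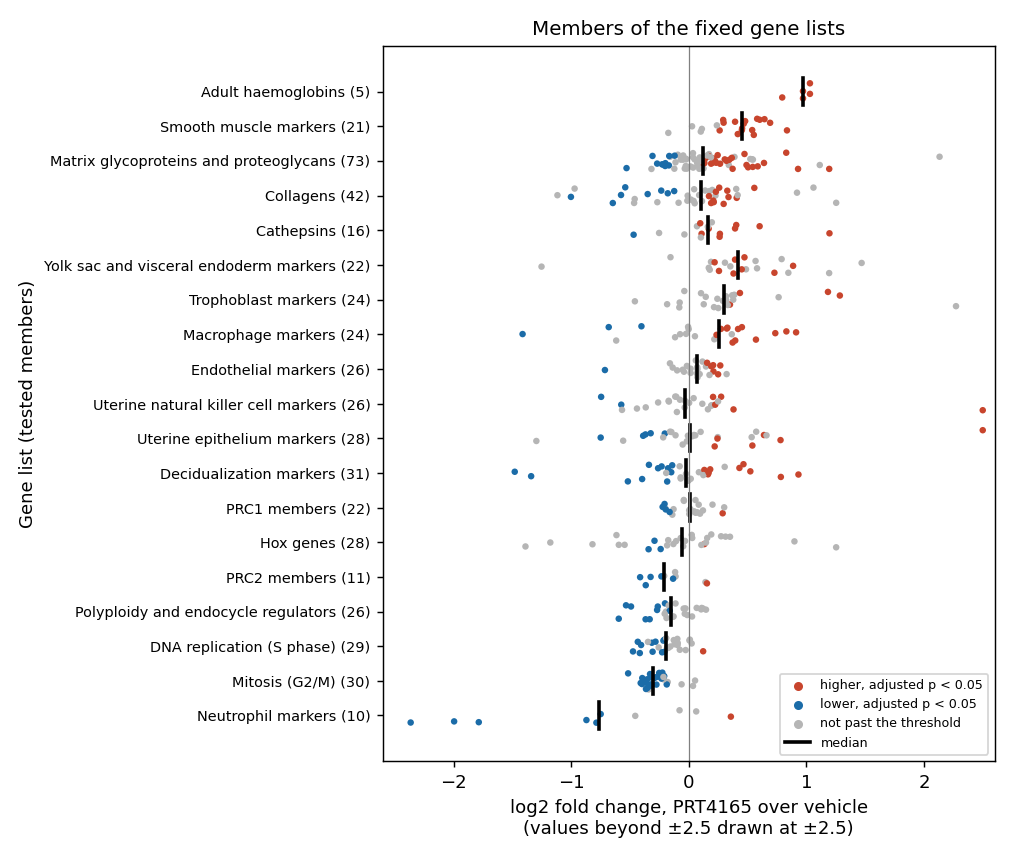
Log2 fold change (PRT4165 over vehicle, horizontal axis) of each tested member of 19 fixed gene lists (vertical axis, with the number tested), coloured by edgeR's adjusted p, with a black bar at each list's median; values beyond ±2.5 are drawn at ±2.5. Medians were 0.97 for adult haemoglobins and 0.45 for smooth muscle markers, and -0.31 for mitosis genes and -0.77 for neutrophil markers.

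Transcripts of the catalytic subunits that PRT4165 inhibits were similar in both groups, which does not measure their activity. Ring1 measured 21.2 ± 2.01 CPM under vehicle and 20.5 ± 0.635 CPM under PRT4165 (log2 fold change -0.042, adjusted p = 0.77). Rnf2 measured 32.6 ± 0.142 CPM under vehicle and 32.7 ± 2.74 CPM under PRT4165 (log2 fold change 0.0046, adjusted p = 0.97), with n = 2 per group. Among 22 tested PRC1 members 1 rose and 4 fell (V1 2/5, V2 4/6, P1 1/0, P2 1/0), the same numbers as when adjusted over the list alone. The falls included the chromatin-binding subunit Cbx2 (log2 fold change -0.21, SE 0.04, adjusted p = 0.0051), Phc3 (-0.22, adjusted p = 0.012) and Bmi1 (-0.20, adjusted p = 0.042). Cbx6, in a row shared with Npcd and overlapping Nptxr, rose by 0.29 on the log2 scale (adjusted p = 0.0011). Cbx4 (log2 fold change -0.14, adjusted p = 0.083) and Rybp (log2 fold change 0.013, adjusted p = 0.89) did not pass the test. The list did not pass (camera adjusted p = 0.82). The falls of Cbx2, Phc3 and Bmi1 did not pass without PRT4165 library 1 (adjusted p = 0.17, 0.17 and 0.37) or without PRT4165 library 2 (0.057, 0.10 and 0.34).

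PRC2, the complex that methylates histone H3 at lysine 27, had lower transcripts for several subunits. Of 11 tested members 5 fell and 1 rose (V1 1/6, V2 2/7, P1 0/2, P2 0/2; 7 and 2 when adjusted over the list alone). Ezh2, its methyltransferase, fell from 32.1 ± 0.719 to 25.6 ± 0.655 CPM (log2 fold change -0.32, SE 0.066, adjusted p = 0.0065). Rbbp7 fell from 271 ± 15.9 to 211 ± 4.83 CPM (log2 -0.37), Mtf2 from 39.2 ± 2.29 to 29.4 ± 0.138 CPM (log2 -0.41) and Suz12 from 63.3 ± 1.25 to 53.9 ± 0.254 CPM (log2 -0.23), with n = 2 per group. The list was lower by camera (median log2 fold change -0.21, adjusted p = 0.034), but not with an estimated correlation (adjusted p = 0.41 with an estimated correlation) nor without vehicle library 1 (adjusted p = 0.069) nor under the stricter filter of 2 CPM (0.061). Without PRT4165 library 1, Ezh2 and Suz12 had adjusted p = 0.14 and 0.15, and without PRT4165 library 2, 0.072 and 0.16.

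Neither Hox genes nor other developmental transcription factors, both classical Polycomb targets, passed camera, although fry called the second list higher. Of 28 tested Hox genes 1 rose and 3 fell (V1 3/4, V2 5/11, P1 0/1, P2 0/1), also when adjusted over the list alone. Hoxa9 fell by 0.34 on the log2 scale (SE 0.061, adjusted p = 0.0031), Hoxd8 by 0.29 and Hoxd9 by 0.24, and Hoxa11, which overlaps an antisense gene, rose by 0.13. Of 49 other developmental transcription factors tested 9 rose and 2 fell (V1 13/3, V2 17/9, P1 2/0, P2 3/2), again the same numbers over the list alone. Dlx3 rose from 1.07 ± 0.363 to 4.13 ± 0.181 CPM (log2 fold change 1.91, SE 0.25, adjusted p = 5.0e-04). Sox11 rose from 1.59 ± 0.191 to 4.05 ± 0.460 CPM (log2 fold change 1.34, adjusted p = 0.0014) and Cdx1 from 0.211 ± 0.138 to 1.52 ± 0.305 CPM (log2 fold change 2.93, adjusted p = 0.0029). Hand2, a stromal regulator of the progesterone response, rose from 1076 ± 0.0741 to 1205 ± 5.19 CPM (log2 fold change 0.16, adjusted p = 0.0023). The risers also included Hand1 and Lhx1, which belong to the trophoblast and early embryo lists too. Whether the rises of this list came from maternal or conceptus cells was not tested. Of the 2 falls, that of Otx2 came from vehicle library 1. The 2 lists had camera adjusted p = 0.50 and 0.24 and fry adjusted p = 0.18 and 0.019. Without PRT4165 library 1 the calls of Hoxd8, Hoxd9, Hoxa11, Cdx1 and Hand2 were lost (adjusted p = 0.26, 0.16, 0.30, 0.071 and 0.071). Those of Hoxd8, Hoxd9, Hoxa11 and Hand2 were lost without PRT4165 library 2 (0.20, 0.13, 0.24 and 0.051), and with library size alone that of Hoxa11 (0.066).

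Decidualization genes went in both directions. Of 31 tested 9 rose and 11 fell (V1 11/15, V2 10/12, P1 5/7, P2 6/7; 10 and 12 when adjusted over the list alone), and the list did not pass camera (adjusted p = 0.76). Fry, which does not compare a list with other genes, called it lower (adjusted p = 0.019). The secreted serine protease Htra1 rose from 701 ± 10.2 to 1338 ± 8.73 CPM (log2 fold change 0.93, SE 0.029, adjusted p = 2.3e-08), with n = 2 per group. Its relative Htra3 rose from 399 ± 14.1 to 687 ± 7.94 CPM (log2 fold change 0.78, SE 0.035, adjusted p = 3.3e-07). Abp1, the diamine oxidase gene, rose from 1121 ± 15.9 to 1548 ± 21.3 CPM (log2 fold change 0.47, SE 0.028, adjusted p = 2.7e-06). Prl8a2, the decidual prolactin and the most abundant of these, measured 6547 ± 599.7 CPM under vehicle and 7362 ± 157 CPM under PRT4165 (log2 fold change 0.17, SE 0.047, adjusted p = 0.028). This call did not hold with library size alone (adjusted p = 0.078) or without PRT4165 library 1 (0.094). Timp3 fell by 1.48 on the log2 scale, and its gene lies within Syn3 on the other strand. Wnt4 fell from 226 ± 8.77 to 179 ± 3.67 CPM (log2 fold change -0.34, SE 0.041, adjusted p = 2.8e-04). Bmp2, which acts upstream of it in decidualization, fell from 559 ± 2.24 to 504 ± 3.22 CPM (log2 fold change -0.15, SE 0.031, adjusted p = 0.0075), but did not pass without PRT4165 library 1 or 2 (adjusted p = 0.19 and 0.14). Hoxa10 measured 403 ± 20.4 CPM under vehicle and 384 ± 8.22 CPM under PRT4165 (log2 fold change -0.069, adjusted p = 0.27), and did not pass. Neither did the progesterone receptor Pgr, at 244 ± 27.6 CPM under vehicle and 213 ± 4.57 CPM under PRT4165 (log2 fold change -0.19, adjusted p = 0.054). Without vehicle library 1 the log2 fold change of Pgr was -0.31, and without vehicle library 2 that of Hoxa10 was -0.12. Such fits take their spread from the close PRT4165 pair alone and do not measure variation among vehicle sites. Pgr itself stood at 224 and 263 CPM in vehicle libraries 1 and 2, and at 210 and 217 CPM under PRT4165.

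The mitosis, DNA replication and polyploidy lists were lower by camera, but not with an estimated correlation (adjusted p = 0.29, 0.30 and 0.74). Of 30 tested mitosis genes 23 fell and 0 rose (V1 0/26, V2 0/23, P1 0/8, P2 0/8; 25 and 0 when adjusted over the list alone). The proliferation marker Mki67 fell from 222 ± 3.21 to 167 ± 0.624 CPM (log2 fold change -0.41, SE 0.037, adjusted p = 3.6e-05). The DNA topoisomerase Top2a fell from 202 ± 1.16 to 162 ± 2.14 CPM (log2 fold change -0.32, SE 0.037, adjusted p = 2.1e-04). The cytokinesis and spindle genes Anln and Nusap1 fell by 0.36 and 0.52 on the log2 scale (adjusted p = 2.7e-04 and 1.6e-04), with n = 2 per group. Of 29 DNA replication genes 11 fell and 1 rose (V1 1/17, V2 1/16, P1 0/2, P2 0/1; 15 and 1 over the list alone), with falls of 0.31 for the helicase subunit Mcm4, 0.47 for Pola1 and 0.43 for the recombinase Rad51 on the log2 scale. The riser was Rrm2, the ribonucleotide reductase subunit and by far the most abundant of the named replication genes (from 3822 ± 6.73 to 4160.1 ± 44.96 CPM; log2 fold change 0.12, adjusted p = 0.0041). Of 26 regulators of polyploidy and the endocycle, by which decidual cells become polyploid, 9 fell and 0 rose (V1 3/9, V2 0/13, P1 0/2, P2 0/2; 10 and 0 over the list alone). Cdk6 fell from 21.3 ± 0.342 to 14.1 ± 0.298 CPM (log2 fold change -0.60, SE 0.08, adjusted p = 5.8e-04), and its partner Ccnd3 from 203 ± 5.65 to 177 ± 1.03 CPM (log2 fold change -0.20, SE 0.038, adjusted p = 0.0044). The inhibitor Cdkn1c fell from 53.2 ± 1.68 to 36.7 ± 0.445 CPM (log2 fold change -0.53, SE 0.057, adjusted p = 1.1e-04), and Ccne2 by 0.49 on the log2 scale (adjusted p = 0.0055).

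In camera these 3 lists had median log2 fold changes of -0.31, -0.19 and -0.15 (adjusted p = 1.3e-10, 8.1e-04 and 0.011; 0.29, 0.30 and 0.74 with an estimated correlation). The polyploidy list did not pass without vehicle library 1 (adjusted p = 0.097) or by fry (0.082). Without PRT4165 library 1, Ccnd3, Ccne2, Rad51 and Rrm2 had adjusted p = 0.12, 0.086, 0.061 and 0.053, and without PRT4165 library 2, Ccnd3, Ccne2, Rad51, Rrm2 and Mcm4 had 0.084, 0.074, 0.097, 0.11 and 0.058.

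Genes of the extracellular matrix were higher more often than lower. Of 73 tested matrix glycoproteins and proteoglycans 25 rose and 10 fell (V1 34/13, V2 33/14, P1 16/1, P2 16/1; 31 and 12 when adjusted over the list alone). The proteoglycan Prelp rose from 157 ± 10.04 to 359 ± 11.98 CPM (log2 fold change 1.19, SE 0.048, adjusted p = 1.5e-07), and the fibulin Fbln2 from 436 ± 15.5 to 775 ± 0.704 CPM (log2 fold change 0.83, SE 0.035, adjusted p = 1.8e-07). The microfibril and collagen-binding genes Mfap4 and Dcn rose by 0.64 and 0.49 on the log2 scale (adjusted p = 9.8e-06 and 5.1e-06), with n = 2 per group. The list was higher by camera (median 0.12, adjusted p = 8.3e-05; adjusted p = 0.29 with an estimated correlation). Of 42 collagens 11 rose and 8 fell (V1 14/8, V2 14/9, P1 10/4, P2 9/5), also over the list alone. Col1a1 rose from 3368 ± 52.8 to 4257 ± 31.6 CPM (log2 fold change 0.34, SE 0.024, adjusted p = 6.8e-06), and Col6a2 and Col5a3 rose by 0.41 and 0.56 on the log2 scale. Col11a1 fell from 79.4 ± 5.42 to 50.7 ± 0.0485 CPM (log2 fold change -0.65, SE 0.057, adjusted p = 3.4e-05). The collagens did not pass as a list (camera adjusted p = 0.45). Smooth muscle markers were higher in the same libraries (median log2 fold change 0.45).

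Proteases and their inhibitors were mixed. Of 46 matrix-degrading proteases and inhibitors 13 rose and 8 fell (V1 17/10, V2 20/9, P1 6/3, P2 6/3; 15 and 8 over the list alone; camera adjusted p = 0.80). Besides Timp3, the aggrecanase Adamts1 fell from 396 ± 3.48 to 259.6 ± 1.80 CPM (log2 fold change -0.61, SE 0.034, adjusted p = 1.4e-06), and Adamts5 and Adamts2 rose by 0.55 and 0.29 on the log2 scale (adjusted p = 4.6e-06 and 1.5e-04). Serpine1, the inhibitor of plasminogen activators, fell from 170.4 ± 0.965 to 63.5 ± 2.59 CPM (log2 fold change -1.42, SE 0.046, adjusted p = 2.3e-08). Serpine2 rose by 0.55, Serpini1 by 2.56 and Serpinb6b fell by 0.55 on the log2 scale; of 32 serpins 8 rose and 7 fell (V1 9/8, V2 11/10, P1 3/5, P2 4/5; 8 and 8 over the list alone; camera adjusted p = 0.50). Of 16 cathepsins 9 rose and 1 fell (V1 9/2, V2 11/1, P1 3/0, P2 3/1; 10 and 2 over the list alone). Ctsk rose from 124 ± 4.89 to 188 ± 1.29 CPM (log2 fold change 0.60, SE 0.042, adjusted p = 6.3e-06). Ctsd, the abundant lysosomal aspartic protease, rose from 490.2 ± 2.32 to 589 ± 16.6 CPM (log2 fold change 0.26, SE 0.034, adjusted p = 3.9e-04). Ctse and Ctsh rose by 1.20 and 0.39 on the log2 scale, although Ctse did not pass without PRT4165 library 1 (adjusted p = 0.054) nor Ctsh without PRT4165 library 2 (0.062). The cathepsins were higher by camera (median 0.17, adjusted p = 0.0040; adjusted p = 0.32 with an estimated correlation). Macrophage markers moved with them in the same libraries (median log2 fold change 0.25).

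Most smooth muscle markers rose. Of 21 tested 16 rose and 0 fell (V1 17/1, V2 17/0, P1 14/0, P2 15/0; 17 and 0 when adjusted over the list alone). Next to Myh11, the actin gene Acta2 rose from 792 ± 6.10 to 1083 ± 3.51 CPM (log2 fold change 0.45, SE 0.028, adjusted p = 3.4e-06). Tagln rose from 651 ± 4.22 to 891 ± 7.34 CPM (log2 fold change 0.45, SE 0.029, adjusted p = 4.1e-06) and calponin Cnn1 from 178 ± 5.81 to 261 ± 0.332 CPM (log2 fold change 0.55, SE 0.039, adjusted p = 6.1e-06), with n = 2 per group. The list was higher by camera (median 0.45, adjusted p = 1.3e-19; adjusted p = 0.20 with an estimated correlation). Undifferentiated stroma markers went both ways, with 4 of 21 up and 6 down (V1 5/8, V2 5/10, P1 4/2, P2 4/2; 4 and 7 over the list alone; camera adjusted p = 0.82). Dpt rose by 0.65, Mfap5 by 0.32 and Des, which is also a smooth muscle marker, by 0.26, and Mme fell by 0.38 on the log2 scale. Of 26 endothelial markers 6 rose and 1 fell (V1 9/3, V2 11/3, P1 0/1, P2 3/1; 8 and 1 over the list alone; camera adjusted p = 0.50). Cdh5 rose from 357 ± 3.89 to 412 ± 8.51 CPM (log2 fold change 0.21, adjusted p = 0.0021), Flt4 by 0.27 and Eng by 0.21 on the log2 scale. The lymphatic marker Lyve1 fell from 97.2 ± 0.692 to 59.3 ± 0.321 CPM (log2 fold change -0.71, SE 0.046, adjusted p = 3.8e-06). The calls of Cdh5, Eng and Flt4 were lost without PRT4165 library 1 (adjusted p = 0.084, 0.12 and 0.20).

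Uterine epithelium markers did not pass camera as a list, but fry called them higher (6 of 28 rose and 5 fell; V1 7/7, V2 11/8, P1 2/2, P2 3/3; 7 and 6 over the list alone; camera adjusted p = 0.13, fry 0.031). Tacstd2, an epithelial surface glycoprotein, rose from 11.2 ± 0.486 to 85.01 ± 2.002 CPM (log2 fold change 2.93, SE 0.064, adjusted p = 3.1e-09). The implantation serine protease Prss28 rose from 253 ± 7.08 to 368 ± 5.12 CPM (log2 fold change 0.54, adjusted p = 5.1e-06). Pigr, the polymeric immunoglobulin receptor, fell by 0.37 on the log2 scale (adjusted p = 0.001) and Lcn2, also a neutrophil gene, by 0.75 (adjusted p = 2.7e-05). Of 9 mesothelium and adipose markers Fabp4 rose by 0.34 on the log2 scale (adjusted p = 3.7e-04). Retn, at 1.16 ± 0.0415 CPM under vehicle and 0.327 ± 0.0530 CPM under PRT4165, was lower (adjusted p = 0.016, lost without either PRT4165 library, at 0.24 and 0.15). Over that list alone 2 rose and 2 fell, and the list did not pass (V1 3/3, V2 1/2, P1 1/0, P2 1/0; camera adjusted p = 0.82).

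Among lists of immune cell markers, the macrophage list was higher and the neutrophil list lower by camera, but not with an estimated correlation (adjusted p = 0.33 and 0.29). Whether numbers of these cells changed was not tested. Of 24 macrophage markers 12 rose and 3 fell (V1 12/4, V2 11/3, P1 6/3, P2 5/3), also over the list alone. Gpnmb, a lysosomal glycoprotein, rose from 813 ± 12.1 to 1445 ± 3.32 CPM (log2 fold change 0.83, SE 0.028, adjusted p = 4.4e-08). It was far more abundant than the other macrophage markers named here, and which cells expressed it was not tested. The receptor Csf1r rose from 163 ± 1.77 to 243 ± 4.32 CPM (log2 fold change 0.57, SE 0.037, adjusted p = 4.1e-06) and Cd68 from 24.5 ± 0.613 to 46.2 ± 1.79 CPM (log2 fold change 0.91, SE 0.064, adjusted p = 6.3e-06). In contrast, the lipid receptor Trem2 fell from 32.8 ± 2.04 to 12.3 ± 0.107 CPM (log2 fold change -1.41, SE 0.079, adjusted p = 1.4e-06), with n = 2 per group. The list was higher by camera (median 0.25, adjusted p = 0.0039; adjusted p = 0.33 with an estimated correlation). Of 10 neutrophil markers 6 fell and 1 rose, also over the list alone. S100a9 fell from 17.2 ± 1.66 to 4.98 ± 0.436 CPM (log2 fold change -1.79, SE 0.12, adjusted p = 4.3e-06). Csf3r fell from 10.05 ± 0.502 to 5.83 ± 0.255 CPM (log2 fold change -0.79, adjusted p = 9.7e-04) and Retnlg from 4.05 ± 0.0536 to 1.01 ± 0.313 CPM (log2 fold change -1.996, adjusted p = 4.6e-04). That list was lower by camera (median -0.77, adjusted p = 3.1e-05; adjusted p = 0.29 with an estimated correlation).

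Uterine natural killer cell markers did not pass as a list (5 of 26 rose and 2 fell; V1 7/3, V2 7/11, P1 2/1, P2 3/1; 6 and 2 over the list alone; camera adjusted p = 0.93). Ctla2a rose from 4499 ± 115 to 5444 ± 7.34 CPM (log2 fold change 0.28, adjusted p = 3.3e-05) and granzyme Gzmb from 129 ± 7.29 to 168 ± 3.53 CPM (log2 fold change 0.38, adjusted p = 3.2e-04). Itga2 fell by 0.57 on the log2 scale, and Cd7 was at 0.149 ± 0.149 CPM under vehicle and 1.37 ± 0.109 CPM under PRT4165 (adjusted p = 0.0045, and 0.054 without PRT4165 library 1). Of 48 chemokines and cytokines 6 rose and 8 fell (V1 10/9, V2 11/13, P1 5/4, P2 5/3), also over the list alone (camera adjusted p = 0.44). The chemokine Cxcl14 rose from 702 ± 16.02 to 1007 ± 7.18 CPM (log2 fold change 0.52, SE 0.031, adjusted p = 2.0e-06) and Cx3cl1 from 37.98 ± 1.75 to 80.5 ± 0.776 CPM (log2 fold change 1.08, SE 0.055, adjusted p = 7.0e-07). Ccl27a, which overlaps Il11ra1 on the other strand, rose from 4.95 ± 0.615 to 19.9 ± 0.843 CPM (log2 fold change 1.996, adjusted p = 1.5e-06). Il11, a cytokine whose signalling decidualization needs, fell from 12.2 ± 0.394 to 4.81 ± 0.498 CPM (log2 fold change -1.34, SE 0.12, adjusted p = 3.5e-05). Of 35 interferon response genes 4 rose and 6 fell (V1 6/7, V2 7/8, P1 2/1, P2 3/0), also over the list alone (camera adjusted p = 0.98). Bst2, Isg15 and Oas2 rose by 0.32, 0.37 and 0.38 on the log2 scale, and Cxcl10 was at 2.82 ± 0.214 CPM under vehicle and 1.06 ± 0.107 CPM under PRT4165 (adjusted p = 0.0035). Isg15 and Cxcl10 did not pass without PRT4165 library 2 (adjusted p = 0.078 and 0.058), nor Oas2 without PRT4165 library 1 (0.087).

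Adult haemoglobin and yolk sac lists were higher under PRT4165 by camera, but not with an estimated correlation (adjusted p = 0.20 and 0.32). All 5 tested adult haemoglobin genes rose, also over the list alone, but Hbb-b1 and Hbb-bs had identical counts, as had Hba-a1 and Hba-a2. Hbb-bs measured 43.6 ± 0.785 CPM under vehicle and 85.4 ± 2.60 CPM under PRT4165 (log2 fold change 0.97, SE 0.052, adjusted p = 9.8e-07), with n = 2 per group. Hba-a1 measured 26.4 ± 1.77 CPM under vehicle and 53.99 ± 0.922 CPM under PRT4165 (log2 fold change 1.03, SE 0.065, adjusted p = 3.4e-06). The list was higher by camera (median 0.97, adjusted p = 3.0e-22; adjusted p = 0.20 with an estimated correlation). Both embryonic haemoglobins tested were higher (V1 3/0, V2 3/0, P1 0/0, P2 1/0), also over the list alone, at low counts. Hbb-bh1 measured 0.281 ± 0.0382 CPM under vehicle and 1.16 ± 0.566 CPM under PRT4165 (adjusted p = 0.018, and 0.51 without PRT4165 library 1). Hba-x had no count in vehicle and 43 in the PRT4165 libraries. It was 10.5-fold higher against a floor of 3 counts over the group, which is not a strict lower bound (adjusted p = 0.02, edgeR). The call was lost without PRT4165 library 2, and was also absent without PRT4165 library 1.

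Of 22 yolk sac and visceral endoderm markers 8 rose and 0 fell (V1 13/0, V2 13/0, P1 2/0, P2 3/0; 11 and 0 over the list alone). Spink3 rose from 57.1 ± 6.21 to 94.95 ± 2.66 CPM (log2 fold change 0.73, SE 0.068, adjusted p = 4.7e-05). Transferrin Trf rose from 16.3 ± 0.935 to 22.3 ± 0.456 CPM (log2 fold change 0.45, adjusted p = 0.0033) and Apoc2 from 2.71 ± 0.370 to 5.04 ± 0.921 CPM (log2 fold change 0.89, adjusted p = 0.0088). The list was higher by camera (median 0.42, adjusted p = 0.0025; adjusted p = 0.32 with an estimated correlation). Trf and Apoc2 did not pass without PRT4165 library 1 (adjusted p = 0.061 and 0.20). Of 24 trophoblast markers 4 rose and 0 fell (V1 8/0, V2 10/0, P1 1/0, P2 2/0), also over the list alone. Prl7a1 rose from 17.1 ± 0.218 to 23.1 ± 0.430 CPM (log2 fold change 0.44, adjusted p = 0.0027). Prl2c3, whose counts equal those of the overlapping Prl2c4, rose from 2.01 ± 0.278 to 4.85 ± 0.524 CPM (log2 fold change 1.28, adjusted p = 0.0011), Tpbpa by 1.18 and Hand1 by 0.35 on the log2 scale. This list did not pass (median 0.30, camera adjusted p = 0.065), although it did without PRT4165 library 2 (0.040), under the stricter filter (0.022) and by fry (0.027). Without PRT4165 library 1, Prl7a1, Tpbpa and Hand1 had adjusted p = 0.061, 0.25 and 0.39, and without PRT4165 library 2, Tpbpa and Hand1 had 0.12 and 0.087.

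Of 13 early embryo markers 2 rose and 1 fell (V1 2/2, V2 2/4, P1 0/0, P2 0/1; 2 and 2 over the list alone; camera adjusted p = 0.93). Lin28a rose from 8.05 ± 0.765 to 11.6 ± 0.212 CPM (log2 fold change 0.52, adjusted p = 0.0075; 0.065 and 0.088 without PRT4165 library 1 or 2). Lhx1 had no count in vehicle and 23 under PRT4165. It was 5.59-fold higher against the floor of 3 counts over the group, again not a strict lower bound (adjusted p = 0.048, edgeR). This call was lost without vehicle library 2, and was also absent without PRT4165 library 1 or 2. Otx2 measured 10.2 CPM in vehicle library 1 and 0.226 CPM in vehicle library 2, against 0.198 and 0.428 CPM in the PRT4165 libraries. Its lower call (adjusted p = 0.037) came from vehicle library 1; without it the log2 fold change was 0.46 (adjusted p = 0.67). Y-linked genes, a marker of male embryos, did not pass the test: of 4 tested 0 rose and 0 fell, also over the list alone (camera adjusted p = 0.82). Ddx3y measured 1.08 ± 0.154 CPM under vehicle and 1.28 ± 0.0582 CPM under PRT4165 (log2 fold change 0.24, adjusted p = 0.65). Kdm5d measured 0.207 ± 0.106 CPM under vehicle and 0.474 ± 0.148 CPM under PRT4165 (log2 fold change 1.14, adjusted p = 0.24).

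Signalling and metabolic lists contained changed genes in both directions and none passed camera. Of 42 BMP and TGF-beta genes 8 rose and 7 fell (V1 8/10, V2 13/9, P1 4/2, P2 4/4; 10 and 10 over the list alone; camera adjusted p = 0.93). The activin and BMP antagonist follistatin Fst fell from 554 ± 43.5 to 387 ± 3.41 CPM (log2 fold change -0.52, SE 0.048, adjusted p = 4.4e-05) and the inhibitory Smad6 by 0.34 on the log2 scale. The activin subunit Inhbb rose from 28.97 ± 1.56 to 45.03 ± 1.16 CPM (log2 fold change 0.63, SE 0.065, adjusted p = 8.7e-05) and Tgfb2 by 0.43. Of 43 WNT genes 6 rose and 5 fell (V1 13/6, V2 13/10, P1 2/3, P2 2/3; 7 and 5 over the list alone; camera adjusted p = 0.82). Besides Wnt4, Wnt5a fell from 216 ± 4.52 to 148 ± 5.42 CPM (log2 fold change -0.55, SE 0.041, adjusted p = 1.0e-05) and Wnt10a from 66.7 ± 1.19 to 43.7 ± 2.25 CPM (log2 fold change -0.61, adjusted p = 4.4e-05). The WNT antagonist Sfrp4 rose from 489 ± 29.8 to 634 ± 1.63 CPM (log2 fold change 0.37, SE 0.041, adjusted p = 1.5e-04). Of 27 steroid and cholesterol genes 8 rose and 5 fell (V1 9/7, V2 10/7, P1 2/3, P2 2/2; 9 and 6 over the list alone; camera adjusted p = 0.45), and fry called the list higher (adjusted p = 0.040). Cyp11a1, the enzyme that starts steroid synthesis from cholesterol, rose from 551 ± 8.25 to 897 ± 11.03 CPM (log2 fold change 0.70, SE 0.031, adjusted p = 2.7e-07) and the cholesterol enzyme Lss by 0.39 on the log2 scale. Hsd3b6 fell from 5.37 ± 0.522 to 2.43 ± 0.307 CPM (log2 fold change -1.15, adjusted p = 0.0014) and Akr1c18, which inactivates progesterone, from 27.1 ± 0.545 to 18.7 ± 1.07 CPM (log2 fold change -0.53, adjusted p = 8.4e-04).

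Of 30 hypoxia and glycolysis genes 6 rose and 5 fell (V1 10/5, V2 9/7, P1 2/3, P2 2/3; 7 and 5 over the list alone; camera adjusted p = 0.77), with Ndrg1 and adrenomedullin Adm up by 0.37 and 0.36 on the log2 scale and Pfkfb4 and P4ha2 down, at -0.36 and -0.27. Of 20 p53 and DNA damage genes 5 rose and 2 fell (V1 5/3, V2 7/4, P1 2/1, P2 2/1; 6 and 4 over the list alone; camera adjusted p = 0.70): Aen, Ddit4l and Trp53inp1 rose by 0.41, 0.73 and 0.25, and Mdm2 fell by 0.28. Of 21 ER stress genes 2 rose and 4 fell (V1 5/5, V2 4/7, P1 1/0, P2 1/0; 2 and 5 over the list alone; camera adjusted p = 0.93), among them Calr and Sdf2l1 at 0.18 and 0.26 and Sel1l and Sesn2 at -0.20 and -0.38. Of 22 immediate early genes, which respond to tissue handling, 6 rose and 2 fell (V1 7/3, V2 8/4, P1 3/0, P2 3/0; 6 and 3 over the list alone; camera adjusted p = 0.44): Socs3, Junb and Jund were at 0.33, 0.32 and 0.30 and Klf6 at -0.20. Of 78 ribosomal protein genes 7 rose and 4 fell (V1 25/7, V2 16/28, P1 3/1, P2 3/2; 5 and 3 over the list alone; camera adjusted p = 0.93), with Rpl35a at 0.77, Rpl41 at 0.29, Rpl39 at -0.22 and Rpl22l1 at -0.47. Without PRT4165 library 1 or 2, Trp53inp1 (0.11 and 0.11), Sdf2l1 (0.20 and 0.055), Sel1l (0.077 and 0.098), Sesn2 (0.083 and 0.19) and Klf6 (0.17 and 0.15) no longer had an adjusted p under 0.05. P4ha2 and Rpl39 did not pass without PRT4165 library 1 (0.076 and 0.074), nor Pfkfb4 without PRT4165 library 2 (0.052).

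In all, camera called 6 of 36 lists higher and 5 lower. It called 0 with an estimated correlation, a version that could hardly call any list from 4 libraries. Fry called 15 lists in 1 direction and 34 in either. The median, mean and test of a list differed in sign for the PRC1, serpin, interferon, ER stress, steroid, ribosomal, early embryo, natural killer, stroma and mesothelium lists, none of which passed camera.

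The largest changes by the fixed rule included several pseudogenes or members of families whose reads the counting could split. Among protein-coding genes, Klk10, a kallikrein protease (chromosome 7, 43781054 to 43785410, mm10), rose from 0.707 ± 0.439 to 10.5 ± 0.174 CPM (log2 fold change 3.80, SE 0.26, adjusted p = 5.5e-06). Its log2 fold change was 3.36 without vehicle library 1 and 4.73 without vehicle library 2. The carbohydrate kinase Fggy (chromosome 4, 95557507 to 95926939) rose from 0.393 ± 0.0361 to 5.03 ± 0.156 CPM (log2 fold change 3.69, SE 0.24, adjusted p = 3.8e-06). Tmem63c (chromosome 12, 87026564 to 87090039) rose from 0.542 ± 0.167 to 4.999 ± 0.173 CPM (log2 fold change 3.24, SE 0.25, adjusted p = 1.3e-05). Serpini1 (chromosome 3, 75557533 to 75642523) rose from 1.55 ± 0.447 to 9.37 ± 0.266 CPM (log2 fold change 2.56, SE 0.18, adjusted p = 7.2e-06). Tchhl1 (chromosome 3, 93468754 to 93471980) rose from 3.90 ± 0.475 to 18.7 ± 1.01 CPM (log2 fold change 2.25, SE 0.12, adjusted p = 8.8e-07). Tacstd2 lies on chromosome 6, 67534059 to 67535822. Cwc22, a splicing factor (chromosome 2, 77895653 to 77946353), fell from 215 ± 12.8 to 25.4 ± 1.20 CPM (log2 fold change -3.08, SE 0.058, adjusted p = 1.3e-09), an 8.48-fold difference. Degs2, a sphingolipid desaturase gene that overlaps Evl on the other strand (chromosome 12, 108686792 to 108702306), fell from 50.2 ± 0.864 to 12.4 ± 0.943 CPM (log2 fold change -2.02, SE 0.074, adjusted p = 6.9e-08). Cst9, a cystatin (chromosome 2, 148835147 to 148838737), fell from 4.53 ± 0.133 to 0.704 ± 0.141 CPM (log2 fold change -2.68, SE 0.24, adjusted p = 4.0e-05).

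The other genes of this set are uncertain. Ear6 (from 5.23 ± 0.0164 to 25.1 ± 0.113 CPM, chromosome 14, 51853768 to 51854642) overlaps Ear7. Pcdhgb8 (from 0.739 ± 0.0454 to 4.86 ± 0.606 CPM, chromosome 18, 37761801 to 37841872) is a polymorphic pseudogene in GENCODE that overlaps other protocadherin genes. The noncoding AA465934 (from 0.373 ± 0.188 to 4.70 ± 0.2998 CPM, chromosome 11, 83291699 to 83294637) overlaps AI450353. The copy of BC002163 on chromosome 16 (from 0.544 ± 0.270 to 7.64 ± 0.341 CPM, 42955580 to 42956079) is a processed pseudogene. So are Gm1821 (from 52.8 ± 8.93 to 4.94 ± 0.353 CPM, chromosome 14, 46084027 to 46084957) and Gm1943 (from 5.65 ± 0.326 to 1.04 ± 0.239 CPM, chromosome 8, 109339800 to 109340908). Znf41-ps (from 4.56 ± 1.81 to 0.126 ± 0.142 CPM, chromosome 4, 145789515 to 145831978), Tmem181b-ps (from 25.4 ± 3.53 to 3.65 ± 0.274 CPM, chromosome 17, 6439002 to 6450994) and Tmem181c-ps (from 10.2 ± 0.0980 to 2.09 ± 0.159 CPM, chromosome 17, 6610103 to 6620925) are unprocessed pseudogenes. A copy of Dynlt1c that overlaps Dynlt1f (chromosome 17, 6648947 to 6655831) had 248 and 334 counts in the vehicle libraries and 0 and 1 under PRT4165. The depth-scaled ratio was 798 (95% counting interval 143 to 31569, too narrow if both mates of a pair were counted). All 20 genes of the set passed edgeR's test with an adjusted p of 4.65e-04 or less.

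**Figure D2:**
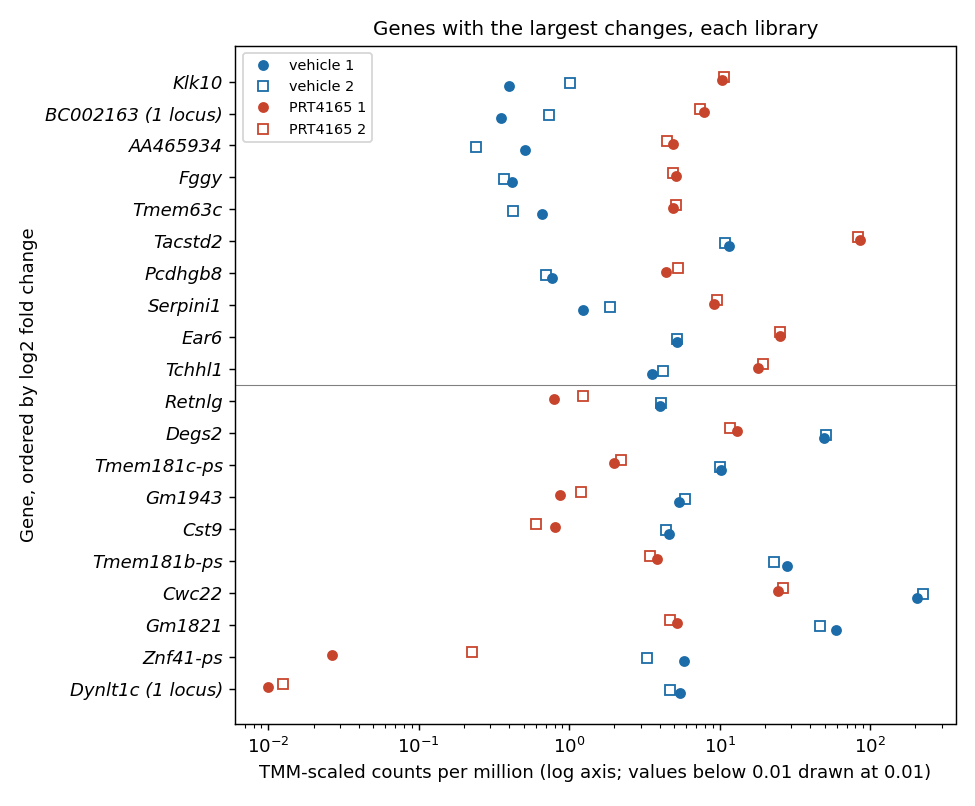
TMM-scaled CPM (horizontal log axis; values below 0.01 are drawn at 0.01) of the 10 largest increases and 10 largest decreases (vertical axis), with 1 point per library, blue for vehicle and red for PRT4165, filled for library 1 and open for library 2. For each gene both PRT4165 points lie beyond both vehicle points, as the rule requires; Tacstd2 averaged 11.2 CPM under vehicle and 85.0 CPM under PRT4165.

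The 2 PRT4165 libraries differed from each other less than the 2 vehicle libraries did. For genes with a mean count of 20000 or more, the coefficient of variation was 1.46% within the PRT4165 pair and 3.24% within the vehicle pair. It was 7.97% to 9.44% between a vehicle and a PRT4165 library, and counting error alone would give 0.767% to 0.787%. At 50 to 200 counts the vehicle pair, at 24.4%, lay between the values of vehicle library 2 with PRT4165 library 1 (23.7%) and with PRT4165 library 2 (24.99%). By correlation of log2 CPM, vehicle library 2 was closer to the PRT4165 libraries (0.9874 and 0.9872) than to vehicle library 1 (0.9835), and the PRT4165 pair stood at 0.9952. Over 14141 genes, chi-square values between the PRT4165 libraries had a median 3.29 times that of a chi-square with 1 degree of freedom (95% bootstrap interval 3.18 to 3.42). The value was 8.37 (8.10 to 8.71) for the vehicle pair, and 18.6 and 17.6 for vehicle library 2 with PRT4165 libraries 1 and 2. Counting both mates of a pair gives 2. The PRT4165 libraries therefore differed beyond counting error and were kept as 2 samples.

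**Figure D3:**
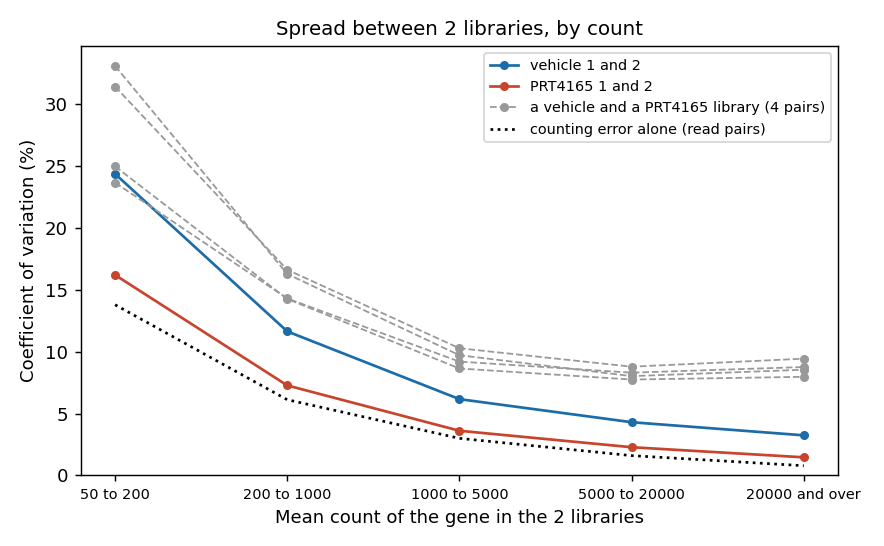
Coefficient of variation (percent, vertical axis) between 2 libraries for genes grouped by mean count (horizontal axis), for the vehicle pair (blue), the PRT4165 pair (red), the 4 pairs of a vehicle and a PRT4165 library (grey) and counting error alone (dotted). At mean counts of 20000 and over the values were 3.24% for the vehicle pair and 1.46% for the PRT4165 pair, with 7.97% to 9.44% between groups.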

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

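The summed libraries, the rows as deposited, the tables without Rn45s, divided counts and the 2-fold minimum were chosen only after the data were seen. The counts of 1731 higher and 1697 lower genes stayed within 1.5 times under the other normalisations, filters, DESeq2, limma-voom, robust dispersion, a threshold of 0.1, divided counts and without Rn45s. They moved to 1148 and 970 on log2(RPKM + 1), and to 1181 and 1026 on log2(RPKM + 0.1), where the cause was not tested. Rows as deposited gave 748 and 597, and the cause was not tested. A fold of at least 1.5 left 412 and 267, and at least 2 left 165 and 118, by construction. Leaving out 1 library gave 646 to 3464 higher and 468 to 3301 lower genes: fewest without PRT4165 library 1 and most without vehicle library 2. Summing the PRT4165 pair to 1 sample gave 708 and 535, and summing the vehicle pair 2884 and 3036; the spread then came from the other pair alone, and the PRT4165 pair was the closer. With the replicate number as a block, the pairing gave 1936 and 1898 genes; the numbers do not pair the samples (correlation of deviations -0.019 over 2 pairs), and no list call changed.

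Lists numbered 6 higher and 5 lower. An estimated correlation left 0 and 0, fry gave 10 and 5 (polyploidy lost and decidualization gained among the lower), the stricter filter gave 7 and 4 (PRC2 lost, trophoblast gained), and leaving out 1 library gave 6 to 8 higher and 3 to 5 lower, with PRC2 and polyploidy lost without vehicle library 1. Of 163 named genes, 155 passed, 109 of them in the same direction under every alternative that gave a value, 110 without any 1 library and 155 under the block. Otx2 reversed to 0.46 without vehicle library 1, which held most of its counts, and was at -5.01 without vehicle library 2. Folds of genes without counts in vehicle, such as Lhx1 and Hba-x, depend on the floor of 3 counts and may be too high where both mates were counted. In simulation at this depth, with the same spread in both groups, 72% of 1.3-fold changes were called.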

Other observations

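The tests of gene position and of other splits of the libraries were set before their results were seen; the gene families, the abundant genes and all other tests in this part were chosen after. Kallikreins, secreted serine proteases encoded in a cluster on chromosome 7 (43690418 to 44229617), were not tested as a set. Of 12 tested 1 by 1, 7 rose and 1 fell (V1 7/1, V2 7/3, P1 5/0, P2 5/0; V1, V2, P1 and P2 as above). Klk6 and Klk1b1, 2 of the 7, did not pass without PRT4165 library 1 (adjusted p = 0.52 and 0.092) or PRT4165 library 2 (0.17 and 0.13). Klk7 rose from 10.99 ± 1.90 to 47.9 ± 1.13 CPM (log2 fold change 2.14, SE 0.10, adjusted p = 4.2e-07, edgeR, n = 2 per group). Klk1 rose from 17.2 ± 0.937 to 30.8 ± 0.235 CPM (log2 fold change 0.85, SE 0.074, adjusted p = 3.1e-05). Klk15 rose from 1.01 ± 0.248 to 3.67 ± 0.138 CPM (log2 fold change 1.83, adjusted p = 5.4e-04) and Klk14 from 2.18 ± 0.0327 to 4.91 ± 0.115 CPM (log2 fold change 1.17, adjusted p = 9.5e-04), next to Klk10 (log2 3.80, and 3.36 and 4.73 without vehicle library 1 and 2). Klk4 fell from 1.27 ± 0.179 to 0.375 ± 0.103 CPM (log2 fold change -1.76, adjusted p = 0.016), but not without PRT4165 library 1 or 2 (adjusted p = 0.12 and 0.24). Klk8 and Klk9, in the same cluster, measured 4.300 ± 0.0857 CPM under vehicle and 4.33 ± 0.814 CPM under PRT4165 (adjusted p = 0.97) and 8.07 ± 1.45 CPM under vehicle and 6.97 ± 0.518 CPM under PRT4165 (adjusted p = 0.35). Of 8 tested CEA family genes 4 rose and 0 fell. Ceacam10, the most abundant of the 4, rose from 37.1 ± 5.89 to 77.2 ± 1.90 CPM (log2 fold change 1.07, SE 0.087, adjusted p = 2.0e-05). Ceacam18 rose by more on the log2 scale, from 1.39 ± 0.288 to 3.44 ± 0.00337 CPM (log2 fold change 1.29, adjusted p = 0.0033). Ceacam2 did not pass, and was at 0.18 without vehicle library 1 and -0.25 without vehicle library 2. Ceacam15, 1 of the 4, did not pass without PRT4165 library 1 or 2 (adjusted p = 0.18 and 0.061). Eosinophil-associated ribonucleases parted: Ear11 fell from 82.7 ± 0.0815 to 22.3 ± 1.33 CPM (log2 fold change -1.89, SE 0.06, adjusted p = 2.3e-08), whereas the overlapping Ear6 and Ear7 rose by 2.26 and 2.18 on the log2 scale and the other 3 of the 6 did not pass. Of 20 prolactin genes 5 rose and 1 fell (V1 7/1, V2 10/1, P1 3/0, P2 5/0). Of 10 granzymes 1 rose and 0 fell (V1 2/0, V2 4/4, P1 1/0, P2 1/0). Members of these families are similar in sequence, and how their reads were assigned is not given in the sources used here.

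Among 2154 abundant genes, with a mean of at least 100 CPM, 35 were higher and 11 lower by at least 1.5-fold. Psap, the precursor of the lysosomal saposins, rose from 13022 ± 344 to 20666 ± 36.4 CPM (log2 fold change 0.67, SE 0.02, adjusted p = 2.1e-08). The phosphoribosyl pyrophosphate synthetase Prps2 rose from 147 ± 12.7 to 632 ± 0.834 CPM (log2 fold change 2.10, SE 0.053, adjusted p = 6.4e-09). The endothelial protein C receptor Procr rose from 122 ± 3.50 to 284 ± 0.768 CPM (log2 fold change 1.22, SE 0.039, adjusted p = 2.3e-08). The acyl-CoA binding protein Dbi rose from 288 ± 5.71 to 537 ± 1.20 CPM (log2 fold change 0.90, SE 0.034, adjusted p = 8.9e-08) and the retroviral sequence Erv3 from 1839 ± 19.8 to 3637 ± 6.26 CPM (log2 fold change 0.98, SE 0.025, adjusted p = 6.4e-09). The stem cell antigen Psca fell from 285 ± 15.9 to 86.1 ± 3.43 CPM (log2 fold change -1.73, SE 0.049, adjusted p = 1.3e-08). The matrix protein Coch fell from 325 ± 36.1 to 107 ± 3.19 CPM (log2 fold change -1.60, SE 0.065, adjusted p = 1.5e-07). Of these 35 higher genes 10 lay on chromosome 2, which held 157 of the 2154 genes, and 9 of the 10 lay between 150 and 170 Mb, among them Procr, Ada, Prex1, Lbp and Tgm2. Over all 12773 genes of at least 2 CPM, 31 of 331 such genes lay on chromosome 2, where its share of genes gives 26.2, and 16 of the 31 lay between 150 and 170 Mb. Of all mapped genes 4.24% changed by at least 1.5-fold, and the stretches of 10 Mb with the highest shares, among those with at least 20 genes, were on chromosomes 17 (0 to 10 Mb, 22.6%), 4 (60 to 70 Mb, 20%) and 10 (0 to 10 Mb, 18.5%). The stretch of chromosome 2 from 150 to 160 Mb came 9th, at 11.6%.

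The PRT4165 libraries were nearly alike and the vehicle libraries less so (correlation 0.9952 and 0.9835), and the count of changed genes rested on the PRT4165 pair. The PRT4165 libraries differed by more than 1 library read 2 times would: their chi-square ratio was 3.29, against 2 for counted mates and 8.37 for the vehicle pair. At most 2 genes were 4-fold apart within a group, against 26 of 12773 genes between the groups, which 1 RNA sample, pool or genotype per group may explain. Vehicle library 2 correlated more with the PRT4165 libraries (0.9874 and 0.9872) than with vehicle library 1, which had the lowest total count. By chi-square ratio, however, the vehicle pair (8.37) was closer than vehicle library 2 with PRT4165 library 1 (18.6) or 2 (17.6). Differences between animals of the groups therefore stay open beside the treatment. Only 3 splits of the 4 libraries exist, too few for a share under 0.05. The real split, with 3428 changed genes, was the 1 split that reached this count. The highest of the others gave 0 by edgeR and by DESeq2, with 36 and 54 genes at an unadjusted p under 0.05 (edgeR). In those splits the difference between vehicle and PRT4165 lies within each group and widens its spread. Any difference between the groups, whatever its source, would give such low counts, so no conclusion is drawn from them.

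Cwc22, several but not all Dynlt1 and Tmem181 copies of chromosome 17 and the BC002163 copy of chromosome 16 differed sharply by group, and Cwc22 lies in a segment known to vary in copy number between mice. Reads moved between the listed copies would leave family sums alike. Yet the summed CPM of the 6 Dynlt1 rows fell by 1.53 and that of the 3 Tmem181 rows by 1.36 on the log2 scale. Of the Dynlt1 rows only 1 copy of Dynlt1c rose, from 31 and 105 counts under vehicle to 190 and 211 under PRT4165. Reads dropped, or assigned to copies outside these rows, would also lower a sum, so shared reads are not excluded. The summed BC002163 copies differed by only 0.24, so its higher copy may come from shifted reads. If the groups carried different haplotypes over long stretches, changed genes would lie together: there were 1277 pairs 1 to 10 Mb apart among 541 genes changed at least 1.5-fold, against a median of 1217 (1096 to 1352) in 2000 shuffles (one-sided permutation p = 0.19), 1120 among as many genes most different within the vehicle pair, and, for the 331 higher genes alone, 514 against 454 (391 to 529; p = 0.052). The counts for all changed and for the higher genes lay above their shuffled medians but within the shuffled range. The 210 lower genes, Cwc22 among them, gave 180 pairs against 182 (149 to 225, one-sided permutation p = 0.54) and showed no such lean. Lying inside that range, the bound set beforehand, excludes no haplotype effect. Strain variants, at single loci such as Cwc22 or over stretches, cannot be told apart from an effect of the treatment.

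Smooth muscle markers rose in 76.2% of the 21 tested, and changes ranged from -0.17 to 0.84 on the log2 scale. A lower share of decidual cells alone would raise every other cell type alike. Yet 4 of 5 other cell types (endothelial 0.074, epithelial 0.011, natural killer -0.033 and neutrophil -0.77) had medians apart from that of smooth muscle (0.45) by more than the spread of its members (0.24). The macrophage median (0.25) did not, nor did those of yolk sac (0.42), mesothelium (0.31) and trophoblast (0.30). Prl8a2 was not lower, but 11 of 31 decidualization markers fell and 9 rose, so a lower decidual share is not excluded. A larger share of uterine muscle in the treated samples may account for the rise, but the markers that define the pattern cannot test it. The abundant Des (from 2886 ± 19.3 to 3463 ± 33.6 CPM), Acta2 (from 792 ± 6.10 to 1083 ± 3.51 CPM), Tagln (from 651 ± 4.22 to 891 ± 7.34 CPM) and Myh11 (from 607 ± 22.3 to 981 ± 7.52 CPM) all rose, although by unequal amounts. All 21 markers were also expressed in the vehicle sites, Des is shared with the stroma list, and Des and Acta2 are made by stromal cells and pericytes too. An effect of PRT4165 on muscle or stromal cells themselves was not tested apart from this.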
